A study of Homo sapiens with 8 samples.

How the data were processed

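RNA levels of 2 human prostate cancer cell lines, LNCaP and PC-3, were measured on 1-colour Illumina HumanRef-8 v3.0 bead arrays, with 1 array per sample. LNCaP was first grown from a lymph node metastasis and is androgen-sensitive, and PC-3 was first grown from a bone metastasis and grows without androgen. Each line had 4 samples, which the series' design text calls biological replicates from different passages. The labels give passages 31 to 32 for LNCaP and 16 to 17 for PC-3, while the growth protocol runs to passages 34 and 19, so which passage each sample came from, and whether samples share one, is not known. Per the labels' protocols the lines were kept in different media with 10% serum for LNCaP and 7% for PC-3, were cultured for 48 h before harvest, and 250 ng of RNA entered each labelling. Line, medium, serum and passage number therefore differ together, and no comparison separates them.

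The deposited table holds 1 value per probe and sample on a log10 scale for 24526 probes. The software, background correction and normalization behind it are not given in the sources used here. The base of the log was read from the values: below 0 the number of probes fell 9.00-fold from the first unit to the next and 9.51-fold from there to the third, as a flat density of small linear levels gives with base 10. Between 12.2% and 16.5% of the probes of an array share that array's lowest value, which lies between -4.83 and -2.72 on the log10 scale and stands in for levels at or below 0. The deposited log10 values had medians from 0.677 to 0.737 and 90th percentiles from 2.265 to 2.289 over the 8 arrays. The levels may be in units of the background's spread, which no source states and which was not tested. Differences between the lines were read for the same probe across arrays, which takes the unit to be alike on all arrays. A level should not be set against that of another probe as an amount of RNA.

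The log10 values were multiplied by 3.32 to give log2 values. A floor was set at the 40th percentile of all values, a log2 level of 1.39 or 2.63 on the linear scale, and all values below it were raised to it. The rule fixed before the data were examined named this floor for linear tables with levels at or below 0, and it was used here because the log10 table carries stand-ins for such levels. No further normalization between arrays was applied, since the upper percentiles lay close together. The rule fixed before the data were examined left out quantile normalization only where columns shared a distribution or stated a normalization. No normalization was stated and the medians differed, so on a strict reading this departed from the rule. Quantile normalization was run as an alternative. Between 57.9% and 61.3% of the probes of an array, 14208 to 15025 probes, lay above the floor. Precision is limited by the number of arrays.

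Probes were named through the array's annotation table as given, and symbols were updated through the gene identifier in NCBI RefSeq's table for GRCh38.p14. The annotation gave 1 gene for 21834 probes, several for 0 and none for 2692. The identifier matched for 21813 probes, and 21 kept the array's own symbol. Where a gene had more than 1 probe, the probe with the highest mean over the 8 samples stood for it, which left 16923 genes. A gene was tested if its mean in the brighter line lay above the median of all values, a log2 level of 2.38, which left 10306 genes and put aside 6617 dim ones. Genes without a pairing in the given tables were not analysed here, and the 3 further label check genes among them are not reported here.

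The lines were compared with limma's lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log2 fold changes are PC-3 minus LNCaP. The design text names an associative test, a published method that pools the spread over a reference set of stable genes. That set is not given, so limma's spread borrowed across genes took its place, and a fit with 1 pooled spread for genes of like level was an alternative. Where any sample of the dimmer line was at the floor, its value there is an upper limit, so the fold is a lower bound and is written as "at least". Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 24 lists. The lists cover androgen response, luminal prostate, epithelial junction, basal epithelial, mesenchymal and integrin genes. Others cover extracellular proteases with their receptors and inhibitors, and NF-kB and cytokine, interferon response, antigen presentation and steroid metabolism genes. Further lists cover cholesterol synthesis, fatty acid synthesis, polyamine, NRF2, p53 target, proliferation, glycolysis and hypoxia, and oxidative phosphorylation genes. The remaining lists cover growth factor receptors with ERBB ligands, and stress, neuroendocrine, cancer testis and other cell type genes. Chromosomes were tested as sets with camera, without the Y chromosome.

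The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes the 6 genes with the largest difference in each direction among those that passed with no overlap between the lines, the label check genes, and for each list the 2 passing members with the largest absolute difference and the 1 with the largest opposite difference. These are 67 genes. Any other gene is said to be chosen after its values were seen.

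The alternatives were quantile normalization, scaling to 1 median, floors at other percentiles, no floor, no filter or a stricter filter on dim genes, the mean of all probes, every probe on its own, other limma settings, the replicate number as a block, and leaving out each sample. Replicates 1 and 2 of both lines differed from replicates 3 and 4, so the array set as a block (also together with camera's estimated correlation and with fry), each array set alone, and the deposited values with no floor were added after seeing the data. Windows of 20 neighbouring genes were compared with 1000 shuffled gene orders, and list means with 10000 random lists matched on level.

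The scripts were tested on simulated data for the comparison of 4 against 4 samples with 10306 genes, of which 200 were changed. At 1.5-fold 38% of the changed genes were recovered and at 2-fold 83%, with 9 false calls among 130. The share of changed genes was far below the 69.8% that differed in the data. Each gene was simulated at the mean of its brighter line, so none was at the floor in 1 line alone. These recovery shares therefore need not hold for the real comparison. The 1 shifted list was called and no other. The simulated genes varied independently of each other, unlike those of some real lists (estimated correlation 0.536 for interferon response). The simulation therefore cannot show how often camera at its preset correlation calls a real list falsely. The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.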

Results

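Expression of 10306 genes was compared between 4 LNCaP and 4 PC-3 samples grown on plastic. Between 14208 and 15025 of the 24526 probes of an array lay above the floor set on the values. Levels are log2 values with the SD over the 4 samples of a line. The passage of each sample is not known and samples may share one, so the p-values measure only the spread between these samples of a line, part of which may be technical.

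The study asked which genes differ between the lines. PC-3 cells had high levels of TIMP1, an inhibitor of matrix metalloproteinases, S100A6, a calcium-binding protein, and CD44, a hyaluronan receptor, all at or near the floor in LNCaP. They also had high levels of GSTP1, a glutathione transferase, CAV1, a structural protein of caveolae, and PLAU, the urokinase plasminogen activator. LNCaP cells had high levels of the steroid glucuronidating enzymes UGT2B7, UGT2B11 and UGT2B28, of the cancer testis antigen GAGE4, of SYT4, a synaptotagmin, and of KLK4, a kallikrein protease. TIMP1 reached 11.66 ± 0.09 (SD, n = 4) in PC-3, while 3 of 4 LNCaP samples were at the floor and 1 was at 1.83, a difference of at least 1140-fold. UGT2B7 reached 10.89 ± 0.17 in LNCaP and was at the floor in all 4 PC-3 samples, at least 719.6-fold lower.

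S100A6 was at least 589.7-fold, CD44 at least 477-fold and CAV1 at least 373-fold higher in PC-3. GSTP1 was at least 444.5-fold and PLAU at least 356-fold higher in PC-3, each with 3 of 4 LNCaP samples at the floor. In LNCaP, UGT2B11 was at least 507-fold, SYT4 at least 454-fold and UGT2B28 at least 263-fold higher. GAGE4 was at least 571-fold and KLK4 at least 311-fold higher, with 2 and 3 of 4 PC-3 samples at the floor. The adjusted p of these 12 genes was at most 1.8e-10 (GAGE4) in the main fit and at most 0.00291 (UGT2B7) over all settings. CD44 had 3 probes, whose log2 differences were 8.90, 5.68 and 2.57. The UGT2B and GAGE genes have near-identical copies that a probe may not separate, so which copy was measured is uncertain.

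In all, 7196 genes (69.8% of those tested) differed, 3685 of them higher in PC-3 and 3511 higher in LNCaP, and 3110 did not pass. The filter kept genes by their level in the brighter line, which favours differing genes. With no filter on dim genes, 6788 of 16923 differed. A difference of at least 2-fold was found for 3838 genes, 2007 higher in PC-3 and 1831 higher in LNCaP. At least 8-fold higher were 441 genes in PC-3 and 302 in LNCaP. Of the differing genes, 378 were at the floor in every LNCaP sample and 301 in every PC-3 sample. The values of the lines did not overlap for 6573 genes (63.8%), where chance gives 2.86%. The median absolute log2 difference of the tested genes was 0.72, against a median standard error of 0.15. Tested against a 2-fold difference with limma's treat, 2386 genes passed. Replicates 1 and 2 of both lines differed from replicates 3 and 4, and the count was 6784 genes within the former set, 5965 within the latter and 7750 with the set as a block.

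**Figure D1:**
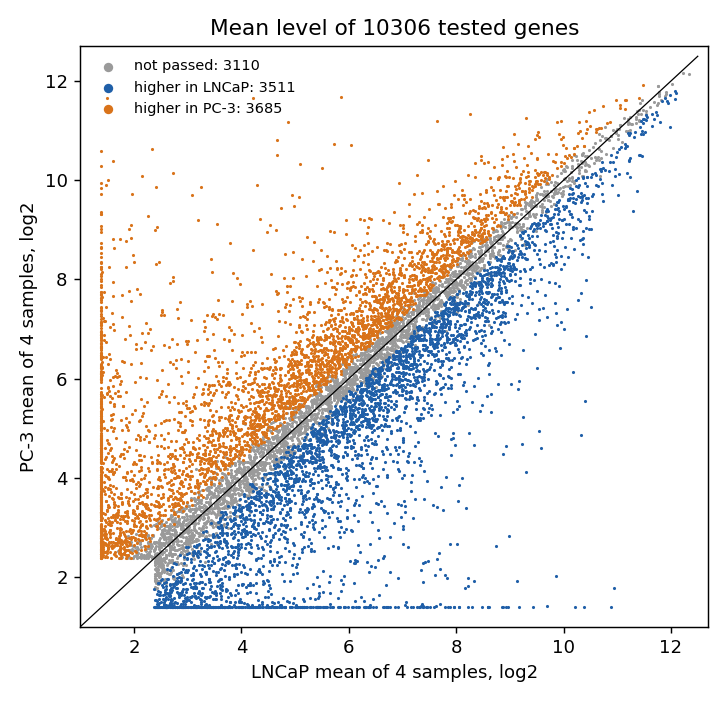
Mean log2 level of 4 PC-3 samples against that of 4 LNCaP samples, with 1 point per tested gene, coloured by the adjusted call. The 3685 genes higher in PC-3 lie above the diagonal, the 3511 higher in LNCaP below it, and points along the left and lower edges are genes at the floor of 1.39 in every sample of a line.

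KLK3, which encodes prostate-specific antigen and is known to be made by LNCaP, had levels of 6.06, 5.69, 6.01 and 5.88 in LNCaP replicates 1 to 4 and was at the floor in all 4 PC-3 samples. CTNNA1, which encodes alpha-catenin and is known to be deleted in PC-3, had levels of 8.64 and 8.67 in LNCaP replicates 1 and 2 and of 8.498 and 8.14 in replicates 3 and 4, and was at the floor in all 4 PC-3 samples. KLK3 was at least 22.9-fold lower (adjusted p = 2.5e-10) and CTNNA1 at least 137-fold lower (adjusted p = 4.8e-11) in PC-3. Both genes were high in the line known to make them.

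**Figure D2:**
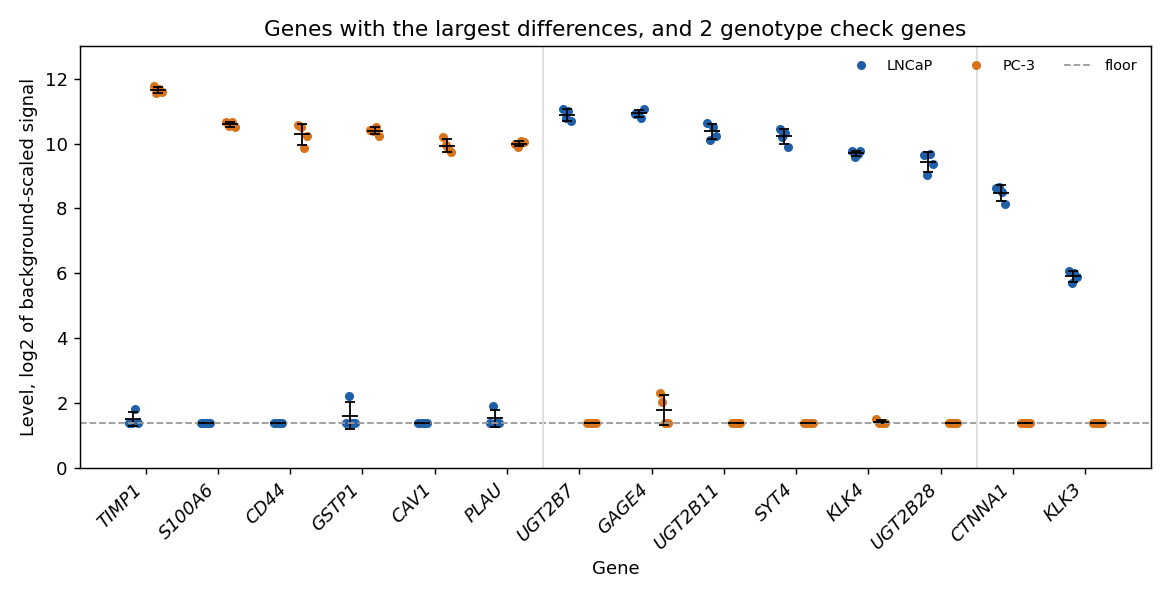
Log2 level per sample (points), mean and SD (bars) in LNCaP and PC-3 for the 6 genes with the largest difference in each direction and for KLK3 and CTNNA1, with the floor of 1.39 as a dashed line. In the dimmer line most of these samples sit on the floor, and GAGE4 reaches 2.30 in PC-3 replicate 1.

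Among lists fixed in advance, genes induced by the androgen receptor were mostly higher in LNCaP. Of 23 tested androgen response genes, 18 were higher in LNCaP, 5 were higher in PC-3 and 0 did not pass, with the same 23 adjusted over the list alone. KLK4 led the list, ACP3, the prostatic acid phosphatase, was at least 31.6-fold higher in LNCaP, and the metalloreductase STEAP4 was at least 13.2-fold higher in PC-3, with 3 of 4 LNCaP samples at the floor. The list's median was -3.60 (camera adjusted p = 3.4e-05), and adjusted p = 0.148 with an estimated correlation. Of 17 luminal prostate markers, 12 were higher in LNCaP, 3 in PC-3 and 2 did not pass, with 15 differing adjusted over the list alone. FOLH1, prostate-specific membrane antigen, was 53.9-fold higher in LNCaP, and keratin KRT19 was 37.8-fold higher in PC-3. The luminal median was -2.16 (camera adjusted p = 0.0146), and adjusted p = 0.298 with an estimated correlation. Chosen after their values were seen, the keratins KRT8 and KRT18 differed by -0.07 and -0.23 and did not pass.

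Of 23 tested steroid metabolism genes (13 more were too dim), 18 were higher in LNCaP, 3 in PC-3 and 2 did not pass, with 21 differing adjusted over the list alone. UGT2B7 and UGT2B11 led this list, and its UGT2B members held the largest differences (-9.49 for UGT2B7 to -6.90 for UGT2B10). Since a probe may not separate their near-identical copies, they may count few transcripts several times. HSD3B1, a hydroxysteroid dehydrogenase, was at least 16.1-fold higher in PC-3, with 2 of 4 LNCaP samples at the floor. The median was -1.83 (camera adjusted p = 3.4e-05), and the call held with an estimated correlation (adjusted p = 0.029) but not with the array set as a block as well (adjusted p = 0.0621). Of 22 cancer testis antigens on the array, 12 were too dim in both lines to test, and the 10 tested were higher in LNCaP, with 10 adjusted over the list alone. MAGEA10 was at least 67.1-fold and MAGEA6 58.2-fold higher, although a second MAGEA10 probe differed by -0.47 and MAGEA genes have near-identical copies. The median was -3.65 (camera adjusted p = 1.2e-06), and this call also held with an estimated correlation (adjusted p = 0.029) and was lost with the array set as a block as well (adjusted p = 0.0621).

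Of 17 fatty acid synthesis genes, 12 were higher in LNCaP, 2 in PC-3 and 3 did not pass, with 15 differing adjusted over the list alone. AMACR, an enzyme of branched-chain fatty acid oxidation, was 18.4-fold and the elongase ELOVL7 at least 9.39-fold higher in LNCaP, while the desaturase FADS1 was 2.03-fold higher in PC-3. The median was -1.02 (camera adjusted p = 0.00138), and adjusted p = 0.148 with an estimated correlation. Of 20 genes known to be induced by p53, 13 were higher in LNCaP, 2 in PC-3 and 5 did not pass, with 15 differing adjusted over the list alone. TP53INP1 was 46.9-fold and the growth factor GDF15 29.0-fold higher in LNCaP, and TP53I3 was 2.66-fold higher in PC-3 on 1 of its 2 probes, the other differing by 0.07. The median was -0.67 (camera adjusted p = 0.0146), and adjusted p = 0.167 with an estimated correlation.

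The basal epithelial markers that could be tested were mostly higher in PC-3. Of 14 on the array, 3 were too dim in both lines to test, the keratins KRT5 and KRT14 among them, which are named after their values were seen, and 7 further members were not analysed here. Of 11 tested, 10 were higher in PC-3 and 1 in LNCaP, with 11 differing adjusted over the list alone. CD44 and CAV1 led the list, and the exception was MME, a membrane metallopeptidase, at least 178-fold higher in LNCaP on the brightest of its 4 probes, which differed by -7.48, -4.44, -2.29 and -0.915. The median was 5.26 (camera adjusted p = 4.6e-05), and adjusted p = 0.0788 with an estimated correlation. Of 16 tested mesenchymal genes (10 more were too dim), 11 were higher in PC-3, 4 in LNCaP and 1 did not pass, with 15 differing adjusted over the list alone. The receptor kinase AXL was at least 252-fold and N-cadherin, CDH2, 129-fold higher in PC-3, while smooth muscle actin, ACTA2, was 7.58-fold higher in LNCaP. The median was 3.06 (camera adjusted p = 0.00402), and adjusted p = 0.0788 with an estimated correlation. Chosen after its value was seen, vimentin, VIM, differed by 3.41.

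Of 12 integrin subunits, 9 were higher in PC-3, 2 in LNCaP and 1 did not pass, with 11 differing adjusted over the list alone. ITGB4 was at least 49.6-fold higher in PC-3 on its brightest probe, with 2 of its 4 probes showing differences of 0.00 and -0.38. ITGA2 differed by 5.32 on the log2 scale, and ITGB7 was at least 2.33-fold higher in LNCaP, with 3 of 4 PC-3 samples at the floor. The integrin median was 1.36 (camera adjusted p = 0.016), and adjusted p = 0.304 with an estimated correlation. Without members that stand in several lists its adjusted p was 0.0894, and over all settings it ran from 2.1e-06 with fry to 0.366 with the array set as a block and an estimated correlation.

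Of 19 NF-kB and cytokine genes, 13 were higher in PC-3, 5 in LNCaP and 1 did not pass, with 18 differing adjusted over the list alone. The chemokine CXCL8 was 78.7-fold and the cytokine IL6 at least 36.3-fold higher in PC-3, while the chemokine CCL20 was 13.2-fold higher in LNCaP. The median was 2.19 (camera adjusted p = 0.0294), and adjusted p = 0.332 with an estimated correlation. The call was also lost with the deposited values and no floor (adjusted p = 0.294), with a started log (0.0579) and in replicates 1 and 2 alone (0.0744), within a range over all settings from 7.0e-07 with fry to 0.464 with the array set as a block and an estimated correlation. Of 30 proliferation genes, 28 were higher in PC-3, 0 in LNCaP and 2 did not pass, with 28 adjusted over the list alone. The mitotic kinases AURKA and BUB1 were 7.15-fold and 4.09-fold higher. They lie on chromosomes 20 and 2, whose tested genes also leaned higher in PC-3 (chromosome medians 0.66 and 0.33). The list's median was 0.95 (camera adjusted p = 1.7e-06), and adjusted p = 0.139 with an estimated correlation.

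**Figure D3:**
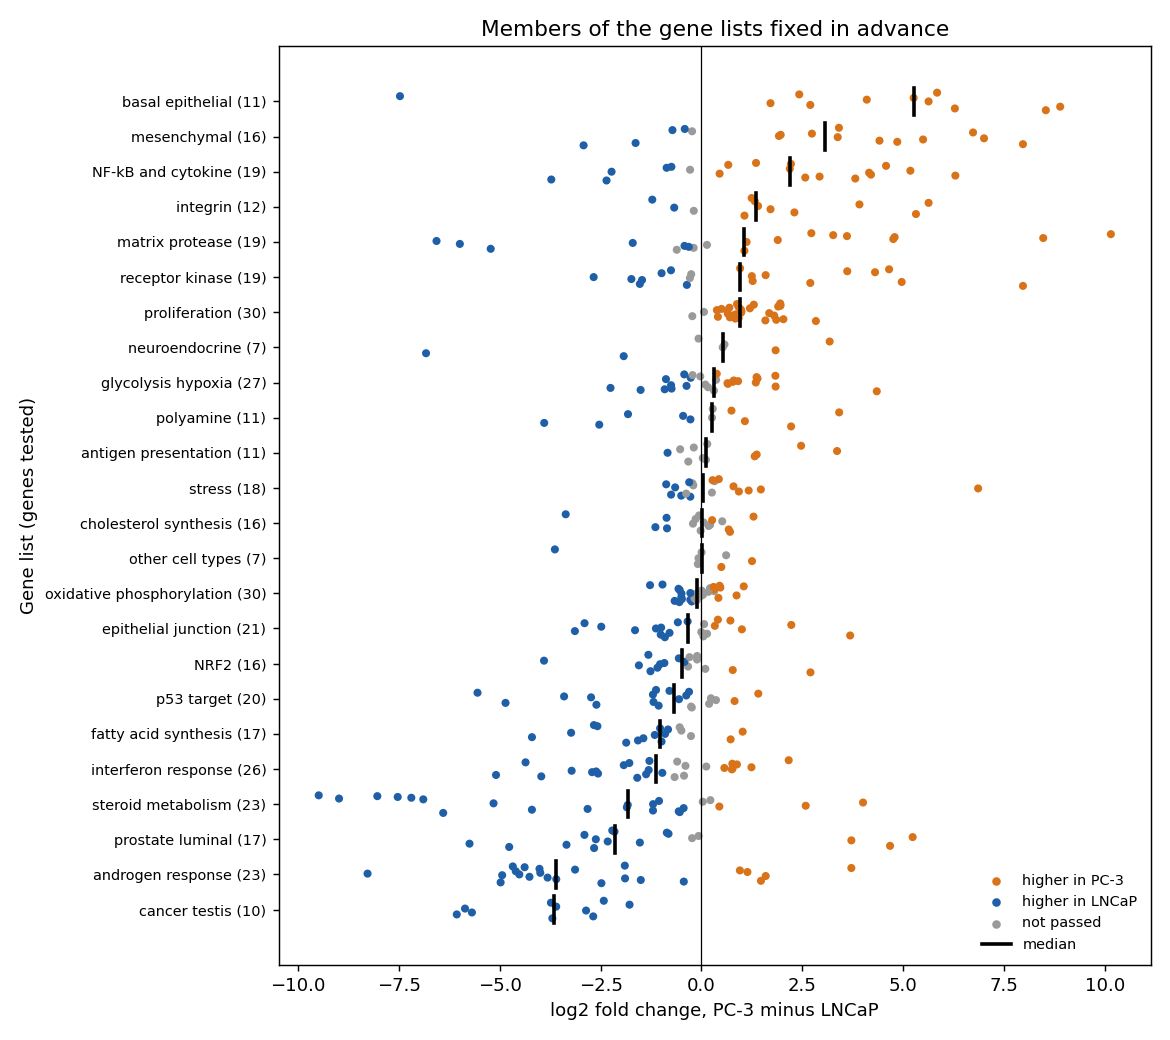
Log2 fold change, PC-3 minus LNCaP, of each tested member of the 24 gene lists, coloured by its adjusted call, with the list's median as a black bar. Medians run from -3.65 for cancer testis antigens to 5.26 for basal epithelial markers.

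The other 13 lists did not pass camera, and each held members that differed in both directions. Of 26 interferon response genes, 14 were higher in LNCaP, 7 in PC-3 and 5 did not pass (21 differing adjusted over the list alone). Here IFI44 was 34.2-fold and OASL 20.6-fold higher in LNCaP, and UBE2L6 was 4.48-fold higher in PC-3 on its brightest probe, with 1 of its 3 probes at the floor in both lines. The interferon median was -1.13 (adjusted p = 0.0609). It passed without LNCaP replicate 2 (0.0267) and without LNCaP replicate 4 (0.0447), within a range over all settings from 0.00846 with fry to 0.873, and the LNCaP samples differed among themselves in the list's mean by an SD of 0.45. Of 21 epithelial junction genes, 11 were higher in LNCaP, 6 in PC-3 and 4 did not pass (17 adjusted over the list alone). Claudin CLDN1 was at least 12.9-fold higher in PC-3, with 2 of 4 LNCaP samples at the floor, and desmocollin DSC2 8.80-fold higher in LNCaP, with a list median of -0.34 (adjusted p = 0.256). Of 19 tested genes for extracellular proteases, their receptors and inhibitors (11 more were too dim), 10 were higher in PC-3. In LNCaP 6 were higher, and 3 did not pass (16 adjusted over the list alone). TIMP1 and PLAU led that list, and the metalloproteinase MMP7 was at least 95.0-fold higher in LNCaP (median 1.07, adjusted p = 0.255). Of 19 genes for growth factor receptors and ERBB ligands, 10 were higher in PC-3, 7 in LNCaP and 2 did not pass (17 adjusted over the list alone). After AXL, the ephrin receptor EPHA2 was at least 31.3-fold higher in PC-3, with 3 of 4 LNCaP samples at the floor. Its log2 difference was 4.97, and 9.42 with the deposited values and no floor, the 1 setting in which its call was lost (adjusted p = 0.059, the highest of all settings). FGFR3 was 6.37-fold higher in LNCaP on 1 of its 2 probes, the other differing by 0.05, and the median of the receptor list was 0.96 (adjusted p = 0.255). The receptor list passed with a stricter filter on dim genes (adjusted p = 0.0459, in a range over all settings from 6.7e-08 with fry to 0.656).

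Among metabolic lists, 16 NRF2 targets had 9 higher in LNCaP, 2 in PC-3 and 5 that did not pass (11 adjusted over the list alone, median -0.49, adjusted p = 0.0608). The cystine transporter SLC7A11 was 15.0-fold higher in LNCaP and AKR1B10 6.52-fold higher in PC-3, and the list passed without LNCaP replicate 4 (adjusted p = 0.0447). It also passed with the array set as a block (0.0493) and with the deposited values and no floor (0.0459), in a range over all settings from 4.2e-06 with fry to 0.258. Cholesterol synthesis had 4 of 16 genes higher in each line and 8 that did not pass (8 adjusted over the list alone, adjusted p = 0.88), with TM7SF2 10.3-fold higher in LNCaP and SQLE 2.45-fold higher in PC-3. Polyamine genes had 5 of 11 higher in LNCaP, 4 in PC-3 and 2 that did not pass (9 adjusted over the list alone, adjusted p = 0.974). Arginase ARG2 was 14.9-fold higher in LNCaP, and SMOX, spermine oxidase, was 10.7-fold higher in PC-3 on 1 of 2 probes. Glycolysis and hypoxia genes had 12 of 27 higher in PC-3, 9 in LNCaP and 6 that did not pass (21 adjusted over the list alone, median 0.31, adjusted p = 0.512). Adrenomedullin, ADM, was 20.4-fold higher in PC-3 and the carbonic anhydrase CA12 4.77-fold higher in LNCaP (log2 difference -2.25, and -1.37 on its other probe). Of 30 oxidative phosphorylation subunits, 12 were higher in LNCaP, 7 in PC-3 and 11 did not pass (18 adjusted over the list alone, median -0.10, adjusted p = 0.461). UQCRC2 was 2.42-fold higher in LNCaP and UQCRB 2.07-fold higher in PC-3.

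Of 11 antigen presentation genes, 4 were higher in PC-3, 1 in LNCaP and 6 did not pass (5 adjusted over the list alone, median 0.11, adjusted p = 0.422). The immunoproteasome subunit PSMB8 was 10.3-fold and the transporter TAP2 5.55-fold higher in PC-3 on the brightest probe of each, and PSMB10 was 1.79-fold higher in LNCaP. The other probes of PSMB8 differed by 3.35, 2.71 and 0.61, and the other of TAP2 by 1.30, against 3.36 and 2.47. Of 18 stress genes, 7 were higher in PC-3, 6 in LNCaP and 5 did not pass (15 adjusted over the list alone, median 0.03, adjusted p = 0.742). The heat shock gene HSPA1A was at least 116-fold higher in PC-3, although its near-identical copy HSPA1B, chosen after its value was seen, differed by -0.65, and HSPB1 was 1.83-fold higher in LNCaP. Of 7 tested neuroendocrine markers (10 more were too dim), 2 were higher in each line and 3 did not pass (4 adjusted over the list alone, adjusted p = 0.88). Dopa decarboxylase, DDC, was at least 114-fold higher in LNCaP and SCG5 at least 9.06-fold higher in PC-3. Of 7 tested markers of fibroblasts, leukocytes and endothelium, 2 were higher in PC-3, 1 in LNCaP and 4 did not pass (3 adjusted over the list alone, adjusted p = 0.975). VWF, an endothelial marker, had a level of 5.03 ± 0.39 (SD, n = 4) in LNCaP and was at the floor in all 4 PC-3 samples, and the leukocyte marker CORO1A was at least 2.39-fold higher in PC-3, with 1 of 4 LNCaP samples at the floor. The other 14 markers of these cell types on the array were too dim to test.

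In all, 11 of 24 lists passed camera, 5 higher in PC-3 and 6 higher in LNCaP, and with an estimated correlation the steroid metabolism and cancer testis calls alone held. With the array set as a block as well, both had an adjusted p of 0.0621. Limma's camera then called 0 lists, with 4 at an unadjusted p under 0.05, and fry called 22. At its preset correlation camera called 12 lists with this block. Without the block, the estimated correlation of mesenchymal genes was -0.0113, below the preset 0.01, yet their unadjusted camera p rose from 0.00117 to 0.0131. It also rose for steroid metabolism genes (-0.019), from 5.7e-06 to 0.00242, and for cancer testis genes (-0.00398), from 4.98e-08 to 0.00126. Correlation between genes therefore need not be why a call was lost. Fry, whose PValue tests whether a set's genes move, on balance, one way, called 23 lists, and its PValue.Mixed, for changes in either direction, called 24. Neither compares a list with other genes. Signs differed within 4 lists. The neuroendocrine median was 0.53 and its mean -0.39, with camera up and fry down. Markers of other cell types had a median of 0.00 and a mean of -0.20, also with camera up and fry down. Polyamine genes had a median of 0.26 and a mean of -0.09, and cholesterol genes 0.02 and -0.17, both down in camera and fry.

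Samples of a line lay close together. The median SD of a gene over the 4 samples was 0.21 in LNCaP and 0.19 in PC-3. Correlations across genes, which are not independent replicates, ran from 0.981 to 0.992 within a line and from 0.745 to 0.760 between the lines. The first principal component held 92.0% of the variance and separated the lines. The next held 3.62% and placed replicates 1 and 2 of both lines apart from replicates 3 and 4. No test of variance was made.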

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

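The tests of the array sets and of their part in the interferon genes were chosen only after the result was seen. Among 103 groups of 4 values of the named genes and 8 of array-wide values, 111 in all, 8 held a sample far from the other 3, all 8 in named genes, where chance gives about 1 in 20 groups, or 5.5 of the 111. In LNCaP, DSC2 was 8.23 in replicate 3 (others 7.83 to 7.87), ITGB7 2.49 in replicate 4 (others 2.72) and TM7SF2 8.94 in replicate 2 (others 9.21 to 9.23). In PC-3 replicate 3, UBE2L6 was 7.75 (others 7.54 to 7.57), PSMB10 8.70 (others 8.33 to 8.37) and SQLE 8.15 (others 8.31 to 8.35). In PC-3 replicate 2, TP53I3 was 5.65 (others 5.34 to 5.39) and HSPA1A 8.46 (others 8.16 to 8.21). In none of these genes did a left-out sample end the call between the lines.

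Other divisions of the 8 samples into 4 and 4 bear on chance. Of 35 splits, 1, the real one, gave 7196 genes, against at most 5 in any other, and 1 gave 3838 genes at least 2-fold apart, against at most 5. This argues against chance for both counts, although 1 of 35 is the smallest share the splits can give. Every other split mixes the lines, which adds the line difference to the spread within groups and lowers its count. The 5 genes came from the split of replicates 1 and 2 from 3 and 4. For the lists, 3 of the 35 splits gave as many as the real 11 (highest other 11), and for the chromosomes 5 gave as many as the real 8 (highest other 9), so by this count chance cannot be excluded for either. The splits as large each kept 3 samples of a line together and so still carried part of the line difference. This count therefore cannot measure chance for lists or chromosomes. Splits with 2 of each line gave at most 3 lists and 0 chromosomes.

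Replicates 1 and 2 of both lines differed from replicates 3 and 4, a division found from these values, with 1180 genes past the threshold, 607 higher and 573 lower in the latter. CLEC2D differed by 3.50 on the log2 scale (3.47 in LNCaP, 3.53 in PC-3) and DRC7 by -2.85 (-2.92 and -2.77). Both were chosen after their values were seen. The set differences of the lines correlated at 0.644 across all tested genes, and noise of dim probes is argued against, since the correlation rose by 0.375 from the dimmest to the brightest of 5 equal groups of genes, where it was 0.880. These correlations, 0.644 and 0.880, argue against drift of each line in genes of its own. Handling shared by both lines and drift of the same genes in each line cannot be told apart. Of the 24 ways to number the PC-3 samples, 4 give a correlation as high. That share of 0.167 is the smallest they can give, so the numberings could not decide. No biological explanation was tested.

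Interferon response genes varied together between LNCaP samples. Their mean lay 0.37, -0.49, 0.40 and -0.28 from the line's mean in replicates 1 to 4, an SD of 0.45 against a median of 0.06 for random lists matched on level, and in PC-3 the SD was 0.03. Chance for a list of this size is argued against by a permutation p of 1e-04, the smallest 10000 random lists can give, and 0.0048 when adjusted over 24 lists and 2 lines. The array set held 0.0226 of the sum of squares, and quantile normalization left 0.957 of the SD, so neither accounts for it. What remains open is a difference between the LNCaP samples, biological or of handling, which may not be one of interferon response alone, since glycolysis and hypoxia genes moved alike (0.14, -0.09, 0.12 and -0.17, permutation adjusted p = 0.0048), as did, without passing, fatty acid synthesis genes (0.0985, -0.11, 0.16 and -0.14, 0.098), and no label separates these samples.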

How the results depend on the processing

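The alternatives with an array set, alone or with another list test, and the one with the deposited values and no floor were chosen after seeing the data. Over all settings the count of differing genes ran from 5837 (stricter filter, fewer genes tested) to 9311 (every probe on its own), and from 6839 to 7041 when any 1 sample was left out. The share higher in PC-3 lay between 47.0% and 54.0%, the latter among genes at least 2-fold apart under treat. Among all differing genes it was 51.2% in the main fit, 48.3% with quantile normalization and 47.0% with scaling to 1 median. Which line had more of the differing genes therefore depended on normalization. Genes at least 2-fold apart ran from 2859 to 5068, and 2386 passed limma's treat, which tests a stricter hypothesis. KLK3 and CTNNA1 kept their calls in every setting run. Of 1673 values for named genes, 1672 kept call and direction, and EPHA2 lost its call with no floor. Of 670 values for lists, 612 kept both, 24 lost the call, 30 gained it and 4 reversed. The reversals were fry's downward calls, with and without the array set as a block, for neuroendocrine markers (median 0.53) and markers of other cell types (median 0.0044), whose few large members outweigh the median. Lists passing numbered 2 with an estimated correlation and 23 with fry. With the array set as a block, 12 passed at camera's preset correlation and 22 with fry. With the block and camera's estimated correlation 0 passed (4 at an unadjusted p under 0.05). The interferon and NRF2 lists gained a call with a floor at the 50th percentile (adjusted p = 0.0359 and 0.043), with no filter (0.0461 and 0.0262) and without LNCaP replicate 4 (0.0447 for both), the interferon list without LNCaP replicate 2 (0.0267) and with the mean of all probes (0.033), and the NRF2 list with the array set as a block (0.0493) and no floor (0.0459). The growth factor receptor list gained one with a stricter filter (0.0459), and the other gains came from fry. Over all settings the adjusted p ran from 0.00846 to 0.873 for interferon and from 4.2e-06 to 0.258 for NRF2. Chromosomes passing fell to 4 with an estimated correlation and to 4 with no filter. The median SD was 0.18 and 0.17 (LNCaP and PC-3) with a floor at the 50th percentile and 0.16 and 0.15 with no filter, where more values sit at the floor. Leaving out 1 sample gave 0.17 to 0.21 in LNCaP and 0.15 to 0.19 in PC-3. The cause of the other changes was not tested. Unmoderated statistics and the pooled spread leave camera unchanged and gave no list values. Signal over background limits the dim genes, since 12.2% to 16.5% of the probes of an array carry its lowest value.

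The replicate number as a block gave 7520 differing genes and 11 lists, and changed no call of a named gene or list. Same-numbered samples of the 2 lines had correlated deviations across genes of 0.38, 0.376, 0.057 and 0.286, and 4 of 8 samples correlated best with their own number, so 1 of the 4 pairs was under 0.1 and the samples were not treated as paired. Within an array set, same-numbered or not, correlations between the lines ran from 0.057 to 0.555, against -0.49 to -0.20 across the sets.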

Other observations

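The window tests below were chosen in advance of their result, while the windows and neighbouring genes named were chosen after their values were seen. Genes of chromosome 20 were mostly higher in PC-3 (194 against 34, median 0.66, camera adjusted p = 1.2e-06) and genes of chromosome 16 mostly higher in LNCaP (272 against 81, median -0.55, adjusted p = 3.2e-05). In all, 8 of 23 chromosomes passed, the others being 2 and 8, higher in PC-3, and 4, 9, 15 and 22, higher in LNCaP. With an estimated correlation 4 passed: 2, 9, 16 and 20, with adjusted p from 0.0218 to 0.0399. In the gene order of GRCh38.p14, used only for which genes neighbour each other, all 20 tested genes from ARFGEF2 to ZFP64 on chromosome 20 were higher in PC-3 (median 1.32). The window with the largest median, 1.85, from EIF2D to SLC30A1 on chromosome 1, was mixed, with 14 genes higher in PC-3 and 4 in LNCaP. On chromosome 8, 18 of 20 from NUDCD1 to SNTB1 were higher in PC-3 (median 1.57), and on chromosome 17, 19 of 20 from ODAD4 to TUBG2 were higher in LNCaP (median -1.83), as were 17 of 20 from ABCA11P to TACC3 on chromosome 4 (median -1.27) and 17 of 20 from SEC63 to HDAC2 on chromosome 6 (median -1.24). SIL1, the tested gene next to CTNNA1 on chromosome 5, differed by -7.20, while HSPA9 on the other side differed by 0.14 and MATR3, beyond SIL1, by -0.14, neither past the threshold.

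A copy number difference between the lines is a candidate explanation for neighbouring genes shifting together. The SD of the medians of 515 windows was 0.50, against at most 0.31 in 1000 shuffled gene orders (permutation p = 0.001, the smallest they can give), which argues against a chance order. With 1 gene per symbol stem and changes limited, it was 0.47 against at most 0.32 (permutation p = 0.001), which argues against clustered families. After removing the trend with level, chromosome 20 kept 0.977 of its median. Of its dimmer genes 74.5% and of its brighter ones 85.6% were higher in PC-3 by sign, against 50.6% of all genes. A gain in PC-3 would give such shares, but so would loss in LNCaP or shared regulation. Chromosome 20 also had the strongest shift of the chromosomes, so high shares in both groups largely follow from that. The shares therefore cannot decide between these causes. DNA was not measured here, and gain in PC-3, loss in LNCaP and shared regulation all stay open.

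Beside the interferon genes, the glycolysis and hypoxia list also varied together between LNCaP samples (0.14, -0.09, 0.12 and -0.17 in replicates 1 to 4, permutation adjusted p = 0.0048). The other 22 lists in LNCaP and all 24 in PC-3 did not pass. The nearest in PC-3 was the NF-kB and cytokine list (-0.15, 0.13, -0.14 and 0.15, permutation adjusted p = 0.054).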
